A study of Homo sapiens with 9 samples.

How the data were processed

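RNA-seq was compared between 3 groups of cultured human cells that the labels call MDA-MB-231, a line established from a triple-negative breast cancer. One group carried a lentiviral short hairpin against GFP, a sequence human cells lack, and served as control (shGFP). The other 2 groups carried separate hairpins against PRMT1 (sh1 and sh2). Each group had 3 libraries from total RNA, which the submitters described as biological triplicates.

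The authors deposited 1 table of FPKM values, fragment counts scaled by transcript length and library size, with a row per Ensembl transcript and a column per library. Per the submitters' processing notes, TopHat2 2.0.8b, Cufflinks 2.2.1, Cuffdiff 2.2.1 and the genome build hg19 were used; the role and settings of each tool were not given in the sources used here. Whether the libraries kept strand was likewise not given, so a gene could not be told apart from an overlapping gene on the opposite strand. The table had 195767 rows. Text in a value column or a missing transcript name removed 16 rows, which left 195751 transcripts of 55867 gene symbols. Of these transcripts, 81.0% were listed at 0 in all 9 libraries.

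A listed 0 was not read as absence of a transcript. PFN1, which every cell uses, was listed at 0 in 6 of 9 libraries and at 257, 977 and 235 FPKM in the others. MT-CO1 and KRT8 were listed at 0 in all 9. These values are sums over all transcripts of a gene, so a shift among its own transcripts does not account for them. Their source was not tested. Single transcripts raise a separate problem. Cufflinks divides reads among overlapping transcripts, so a transcript can pass from a high value to 0 between libraries while its gene hardly moves. Such switching transcripts occurred in 45.1% of the tested genes and in 35.4% of the genes called with sh1.

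The column of shGFP replicate 1 was incomplete. Of 11828 transcripts above 0 in all other libraries, 6153 (52.0%) were listed at 0 in that column. Its FPKM summed to 318878, against 501889 to 525295 in the other 8 libraries. A gene counted as listed in this library if it was above 0 there and none of its transcripts above 0 in all other libraries was at 0. Genes called as changed with either hairpin in a fit without this library were listed in it more often (67.9% of 3393) than genes not called (38.4% of 6023). The design fixed beforehand used all 9 libraries. The fit reported here left out shGFP replicate 1, which was decided after the table had been examined, so shGFP had 2 libraries and each hairpin 3. Counts from the design as first written stand beside the main counts. PRMT1 and CCND1 were listed in full in all 9 libraries, and their levels and permutation tests used all 9.

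Rows of the same symbol were summed. A gene was tested if its mean over the 8 libraries was at least 1 FPKM and it was above 0 in each of them, which gave 9416 genes, 8989 of them protein-coding in GENCODE 29, and left out 1162 of 10578 genes above the mean. Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean trend), with a coefficient per group and Benjamini-Hochberg adjustment, two-sided, at an adjusted p of 0.05. All adjusted p-values for genes come from this test. A fold change on the log2(FPKM + 1) scale understates the change of genes listed at low values. The comparisons were sh1 against shGFP, sh2 against shGFP, their mean against shGFP, and sh2 against sh1. The table holds no read counts, so the depth behind each value was unknown and no counting interval could be given.

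Before the data were examined, 31 gene lists, the alternatives and the rule for named genes were written down. The rule took PRMT1, CEBPA, CCND1 and HDAC3; the 8 largest rises and falls per hairpin among called genes whose knockdown libraries all lay to the same side of the shGFP libraries (replicates 2 and 3); the 10 rises and 10 falls with the largest smaller change among genes called with both hairpins; the 5 largest rises and falls between the hairpins; and in each list the 4 tested members that changed most plus those called with both hairpins. A list of 25 melanocyte lineage genes and a list of 18 keratin and epithelial surface genes were added after the first gene table had been seen, when 5 of the melanocyte genes (TYRP1, DCT, GPR143, MLPH and BIRC7) had been noticed and KRT7, KRT8 and KRT19 had been seen at 0. Lists with at least 3 tested genes were compared with all other genes by camera with a preset inter-gene correlation of 0.01, adjusted over 28 lists, and again with an estimated correlation. In the 25 of 112 list tests that passed, median, mean and test had the same sign; in 15 of the others they did not. Of the 25 calls, 2 passed with the estimated correlation, namely the mesenchymal and the melanocyte lists with sh1. The estimate lay above the preset 0.01 for some called lists, such as the ribosomal list (0.25). It lay below 0.01 for others, such as the mesenchymal (-0.024) and C/EBP (-0.025) lists. The mesenchymal camera p with sh1 still went from 2.0e-08 to 0.0018. In such lists the weaker value does not come from correlation among members, because this setting changes more of the test than the correlation. The melanocyte list held the 5 genes seen beforehand, so its camera test is not independent of the data. Without them its sh1 call was lost with the estimated correlation (adjusted p = 0.052). The mesenchymal value with sh1 (adjusted p = 0.025) was adjusted with the full melanocyte list ranked ahead of it. Ranked first of 28 lists, ahead of the shortened melanocyte list, its camera p of 0.0018 would not reach an adjusted p of 0.05. No list call with the estimated correlation is then left.

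Permutation tests and figures used Python 3.11.15, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The fit was tested on simulated data of 9416 genes with 200 changed. It recovered 70% of log2 changes of 1 with each hairpin and 74% with their mean, and 18%, 19% and 25% of log2 changes of 0.5. False calls made up 4.35%, 5.32% and 2.94%. The simulation gave 92 calls with sh1, against 2278 in the data, and the adjustment is stricter where fewer genes change. Its errors were normal, independent between genes and drawn with the spread of the fit itself, without switching transcripts. The shares recovered and the shares of false calls therefore need not hold for the data. Alternatives covered the pseudocount, the filter, the scaling, the replicate number as a block, the groups in the fit, the variance model, transcript rows in place of symbols, and each library left out in turn. Further alternatives, chosen after the table had been seen, covered the treatment of shGFP replicate 1 and of listed zeros, and the melanocyte list without the 5 genes.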

Results

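The data were transcript FPKM values from 9 RNA-seq libraries of cells labelled MDA-MB-231, 3 each with a control hairpin (shGFP) and with hairpins sh1 and sh2 against PRMT1, the main enzyme that places asymmetric dimethyl marks on arginine. The series concerns PRMT1, the transcription factor C/EBP alpha (CEBPA) and transcription of cyclin D1 (CCND1). Each hairpin was compared with shGFP, and the hairpins with each other, over 9416 genes. The FPKM of the 8 libraries used in the fits summed to between 501889 and 525295; the depth in reads was unknown.

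PRMT1 (ENSG00000126457) was lower in every knockdown library than in every control library. It stood at 179 ± 8.72 FPKM (SD, n = 3) with shGFP, 57.7 ± 1.97 (SD, n = 3) with sh1 and 72.5 ± 4.74 (SD, n = 3) with sh2, that is, 32.3% and 40.6% of the control mean. CCND1 (ENSG00000110092), the D-type cyclin that activates CDK4 and CDK6 in G1, stood at 189 ± 5.16, 61.2 ± 7.85 and 90.7 ± 2.23 FPKM (SD, n = 3 each), 32.4% and 48.1% of the control. An exact two-sided permutation test of the 6 knockdown against the 3 control libraries gave p = 0.0238 for each gene, the smallest that 84 splits allow. The test treats all libraries as exchangeable, although the knockdown libraries form separate sh1 and sh2 groups. It gives this p whenever all control libraries lie to the same side of the others. It therefore cannot tell knockdown from another difference of the control culture. In the fit, PRMT1 fell with sh1 (log2 change -1.59, SE 0.07, adjusted p = 3.9e-05) and with sh2 (-1.26, SE 0.07, adjusted p = 9.7e-05). CCND1 fell with sh1 (-1.63, SE 0.10, adjusted p = 0.00013) and with sh2 (-1.06, SE 0.10, adjusted p = 0.0008). Of the 3 tested study genes (PRMT1, CCND1 and HDAC3), 2 fell with each hairpin (2 adjusted over the list alone). Camera gave adjusted p = 0.037 and 0.036 with sh1 and sh2, and 0.17 and 0.22 with an estimated correlation. PRMT1 is the target of both hairpins, so the list call in part restates the knockdown. The list call was lost without sh1 replicate 1 for sh1 (adjusted p = 0.083), and without shGFP replicate 3 or sh1 replicate 2 for sh2 (adjusted p = 0.051 and 0.057). Both genes were higher with sh2 than with sh1, PRMT1 by a log2 difference of 0.32 (adjusted p = 0.013) and CCND1 by 0.57 (adjusted p = 0.0066). The PRMT1 difference between hairpins did not pass with all 9 libraries and their zeros as values (adjusted p = 0.054) or with transcripts tested separately (0.23, adjusted p = 0.17).

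**Figure D1:**
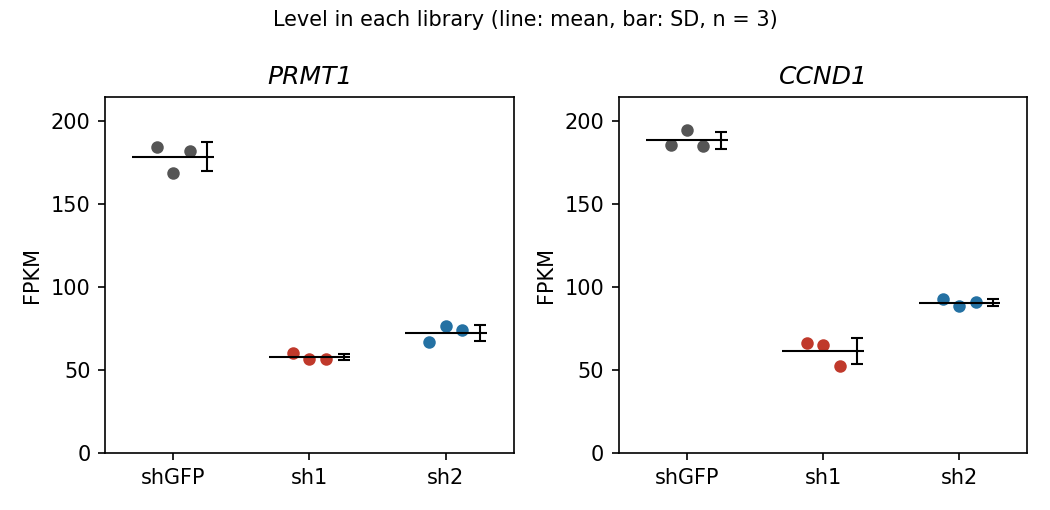
FPKM of PRMT1 and CCND1 in each of the 9 libraries, by group; points are libraries, lines means and bars SD (n = 3). The sh1 and sh2 libraries of each gene all lie below the shGFP libraries, with PRMT1 means of 57.7 and 72.5 against 179 FPKM.

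HDAC3, a histone deacetylase, was at 26.1, 27.5 and 24.6 FPKM with shGFP, sh1 and sh2 and passed with neither hairpin (log2 changes 0.07 and -0.08, adjusted p = 0.59 and 0.52). CEBPA was below 1 FPKM in every library, at 0.168 and 0.133 in 2 shGFP libraries, at 0.274 ± 0.120 with sh1 and at 0.584 ± 0.0932 with sh2 (SD, n = 3), and was listed at 0 in shGFP replicate 1. With the filter lowered to 0.1 FPKM, CEBPA was higher with sh2 (log2 change 0.46, adjusted p = 0.017) and did not pass with sh1 (0.14, adjusted p = 0.36) or between the hairpins (0.32, adjusted p = 0.051). Of the 4 tested genes on the C/EBP list (CEBPB, CEBPD, CEBPG and CEBPZ), all 4 fell with sh1 (4 adjusted over the list alone). Camera gave an adjusted p of 0.0091, and 0.11 with an estimated correlation. With sh2, 1 of the 4 rose and 2 fell (1 and 3 adjusted over the list alone). CEBPZ belongs to the family by symbol only, so these counts and tests are not those of the family alone. CEBPD fell with sh1 (-0.70) and sh2 (-0.86; adjusted p = 0.0045 and 0.0021). CEBPB fell by 0.52 with sh1, a call lost without shGFP replicate 3, and rose by 0.70 with sh2 (adjusted p = 0.01 and 0.0032).

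The first comparison asked which genes change with sh1. The matrix genes THBS1, TGFBI and FN1 fell, as did CDC20 and RRM2, which act in mitosis and DNA synthesis, while the melanosome gene PMEL and the antiviral gene BST2 rose. In all, 2278 genes differed from shGFP, 1163 higher and 1115 lower, and 313 of them by a log2 change of at least 1. The rankings here, with sh2 and between the hairpins leave out genes listed at 0 in any of the 8 libraries. TCFL5, for example, was listed at 0 in every shGFP and sh2 library and at 36.4, 37.9 and 43.1 FPKM with sh1. A listed 0 may be a failed estimate, so its change was not ranked. The largest rises were of PCSK1N, an inhibitor of a prohormone convertase (0.782 to 23.0 FPKM, log2 change 3.75), BIRC7, an inhibitor of apoptosis (1.53 to 30.5 FPKM, 3.64), BST2, the antiviral tetherin (0.544 to 15.8 FPKM, 3.44), and GDF15, a secreted stress cytokine (10.1 to 109 FPKM, 3.32). SYNGR1, the elongation factor EEF1A2, the convertase PCSK6 and the CD47 receptor SIRPA rose by 2.97, 2.83, 2.69 and 2.57; over its transcripts listed in every library SIRPA changed by 1.87, and by 2.22 with sh2. TMEM163 fell from 11.4 to 0.129 FPKM (log2 change -3.46). THBS1, which encodes the matrix protein thrombospondin 1, fell from 234 to 44.2 FPKM (-2.37), and TGFBI, another matrix protein, from 15.2 to 0.900 (-2.98). NRCAM, the ectonucleotidase NT5E, the metalloprotease ADAM19, the glycosyltransferase GALNT1 and fibronectin (FN1) fell (log2 changes -2.18, -2.04, -2.01, -1.98 and -1.98). The standard errors of these changes were 0.38 for TGFBI, 0.42 for GALNT1, 0.25 for SYNGR1 and between 0.07 and 0.16 for the others, and the GALNT1 call (adjusted p = 0.016) was lost without shGFP replicate 2. Without shGFP replicate 2 the count was 1362, without shGFP replicate 3 it was 1343, and with all 9 libraries and their zeros as values it was 1242; with replicate 1 of shGFP used only for genes it lists it was 2422.

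Of the 16 tested mesenchymal genes, 10 fell and none rose with sh1 (14 adjusted over the list alone). Camera gave an adjusted p of 2.8e-07, and 0.025 with an estimated correlation. The value of 0.025 would not pass with the melanocyte list limited to the genes not seen beforehand. Beside TGFBI and FN1, the genes that fell included S100A4, a calcium-binding protein tied to motility (277 to 95.3 FPKM, log2 change -1.53). LOXL2, which cross-links collagen, fell as well (39.3 to 20.8 FPKM, -0.89). Of 14 tested TGF-beta and YAP targets, 8 fell and 1 rose (9 and 2 adjusted over the list alone; camera adjusted p = 0.0012, and adjusted p = 0.062 with an estimated correlation), among them THBS1 and CYR61 (-0.58, a call lost without shGFP replicate 2). Of 29 tested mitosis genes, 15 fell and none rose (17 adjusted over the list alone; camera adjusted p = 6.6e-06, and adjusted p = 0.062 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, went from 256 to 142 FPKM (-0.85), cyclin B1 (CCNB1) from 181 to 125 (-0.53) and NDC80, a kinetochore protein, from 25.1 to 17.4 (-0.50). Of 30 tested DNA replication genes, 11 fell and none rose (13 adjusted over the list alone; camera adjusted p = 0.00052, and adjusted p = 0.062 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, fell by 0.63, TYMS, thymidylate synthase, by 0.48 and the sliding clamp PCNA by 0.35.

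Of 24 tested interferon-stimulated genes, 7 rose and none fell with sh1 (7 adjusted over the list alone; camera adjusted p = 0.0011, and adjusted p = 0.062 with an estimated correlation). Beside BST2 they included OAS1, a sensor of double-stranded RNA (0.234 to 3.18 FPKM, log2 change 1.76), IFI35 (17.7 to 38.0 FPKM, 1.06) and IFI6 (33.2 to 57.7 FPKM, 0.78). IFI35 and IFI6 had no switching transcripts, and BST2 changed by 3.57 over its transcripts listed in every library. OAS1 had no such transcript, and those of ISG20, which also rose, were below the filter. IFIH1 rose by 0.54, but over such transcripts it changed by 0.06 and did not pass (limma adjusted p = 0.73). Of the 20 tested melanocyte lineage genes, the list added later, 14 rose and 1 fell (17 and 1 adjusted over the list alone; camera adjusted p = 1.0e-09, and adjusted p = 0.022 with an estimated correlation), in the same libraries as the groups above. Of these, 5 had been seen in the gene table before the list was written, and each of the 5 rose. Of the other 15, 9 rose and 1 fell (11 and 1 adjusted over the list alone; camera adjusted p = 1.5e-05, and adjusted p = 0.052 with an estimated correlation). DCT, an enzyme of melanin synthesis, went from 70.5 to 280 FPKM (1.97), PMEL, a melanosome matrix protein, from 211 to 754 (1.82) and RAB38, which takes part in melanosome transport, from 34.6 to 95.6 (1.44). MCAM, a melanoma-associated adhesion molecule, fell by 0.53.

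The second comparison asked the same of sh2. MCM4 and TYMS, which act in DNA replication, the mitotic gene CDC20 and the matrix genes THBS1 and TGFBI fell, and the glycolytic enzyme genes ENO2 and TPI1 rose. In all, 2403 genes differed from shGFP, 1146 higher and 1257 lower, and 303 of them by a log2 change of at least 1. The largest rise was of GPR143, a melanosome receptor, from 0.112 to 43.7 FPKM (log2 change 5.33). BIRC7 (3.92), EEF1A2 (3.90), CASP1, the inflammatory caspase (2.02 to 28.3 FPKM, 3.28), GDF15 (3.13), PCSK6 (2.99), SIRPA (2.98) and BST2 (2.89) followed. TYRP1, an enzyme of melanin synthesis, fell from 234 to 49.0 FPKM (-2.23), THBS1 from 234 to 48.3 (-2.25), TGFBI from 15.2 to 1.71 (-2.51) and FAIM3, a receptor for IgM, from 15.8 to 1.48 (-2.75). The transcription factors RUNX1 and MAF fell (-2.10 and -1.90). Over its transcripts listed in every library RUNX1 changed by -1.33 and TYRP1 by -3.41; GPR143, CASP1, PCSK6 and TGFBI had no such transcript, and those of MAF were below the filter. VTI1B and PCM1 also met the rule (log2 changes -2.09 and -1.96), but over their transcripts listed in every library the changes were -0.00 and -0.53 and passed for neither; the VTI1B call was also lost without shGFP replicate 2 or 3. Standard errors were between 0.35 and 0.43 for FAIM3, TGFBI, RUNX1 and VTI1B and between 0.06 and 0.17 for the others. Without shGFP replicate 2 the count was 1447, without shGFP replicate 3 it was 1460, and with all 9 libraries and their zeros as values it was 1337; with replicate 1 of shGFP used only for genes it lists it was 2513.

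With sh2, 16 of the 30 tested DNA replication genes fell and none rose (20 adjusted over the list alone; camera adjusted p = 6.4e-06, and adjusted p = 0.12 with an estimated correlation). MCM4, part of the replicative helicase, went from 120 to 63.8 FPKM (log2 change -0.90) and TYMS from 308 to 189 (-0.70). Of 29 mitosis genes, 12 fell and 1 rose (14 and 1 adjusted over the list alone; camera adjusted p = 0.0084, and adjusted p = 0.22 with an estimated correlation), with CDC20 at -0.50 and CCNB1 at -0.47. Of 20 tested hypoxia and glycolysis genes, 6 rose and none fell (8 adjusted over the list alone; camera adjusted p = 0.0019, and adjusted p = 0.12 with an estimated correlation). The neuronal enolase ENO2 went from 16.9 to 63.6 FPKM (1.85), TPI1, triosephosphate isomerase, from 501 to 692 (0.46), and hexokinase HK1 rose by 0.34, all 3 of them glycolytic enzymes. With sh1, 7 members of that list rose and 3 fell (8 and 4 adjusted over the list alone, camera adjusted p = 0.37). ENO2, TPI1 and HK1 rose with sh1 too (1.88, 0.60 and 0.23). None of these 3 genes passed between the hairpins (adjusted p = 0.65, 0.080 and 0.12), nor did the list (camera adjusted p = 0.12). Of 27 ribosomal protein genes, 9 fell and none rose with sh2 (12 adjusted over the list alone; camera adjusted p = 0.018, and adjusted p = 0.54 with an estimated correlation), among them RPL13 (-0.62) and RPL27 (-0.38); the list call was lost without shGFP replicate 3 (adjusted p = 0.052). With sh1, 5 fell and none rose (5 adjusted over the list alone; camera adjusted p = 0.15).

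Of the 16 mesenchymal genes, 7 fell and 1 rose with sh2 (8 and 2 adjusted over the list alone; camera adjusted p = 0.049, and adjusted p = 0.22 with an estimated correlation); the call was lost in 6 of the 8 fits that left out a library. FN1 fell by 1.05, LOXL2 by 0.89 and CD44, the hyaluronan receptor, by 0.41. Of 14 TGF-beta and YAP targets, 5 fell and 2 rose (5 and 2 adjusted over the list alone; camera adjusted p = 0.51), with CYR61 at -1.32. Of 24 interferon-stimulated genes, 6 rose and 2 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.092), with IFI35 at 0.73. Of 20 melanocyte lineage genes, 8 rose and 3 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.018, and adjusted p = 0.22 with an estimated correlation), with PMEL at 1.41, RAB38 at 0.89 and DCT at -0.49. Of the 15 not seen beforehand, 6 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.011, and adjusted p = 0.19 with an estimated correlation).

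**Figure D2:**
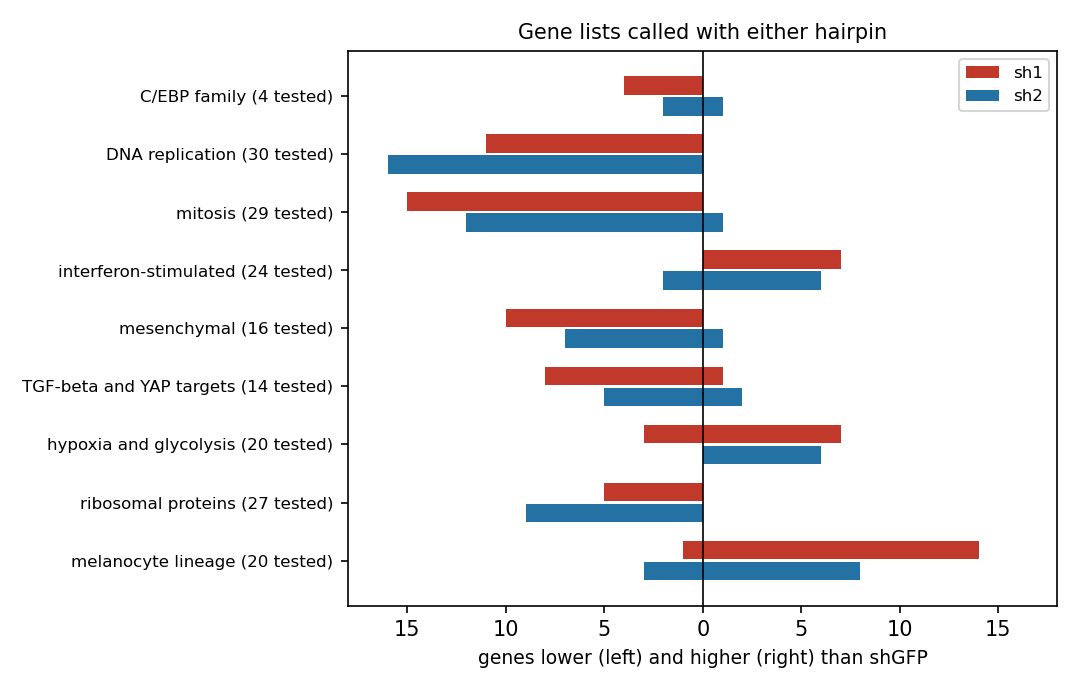
Number of genes lower (left) and higher (right) than shGFP at an adjusted p of 0.05, with sh1 and sh2, in the gene lists called with either hairpin other than the study genes. With sh1, 15 of 29 mitosis genes were lower, and 14 of 20 melanocyte lineage genes were higher.

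With both hairpins in the same direction, 1212 genes were called, 642 higher and 570 lower. Without shGFP replicate 2 the count was 707, without shGFP replicate 3 it was 704, and with all 9 libraries and their zeros as values it was 639; with replicate 1 of shGFP used only for genes it lists it was 1335. BIRC7, GDF15, BST2, EEF1A2, PCSK6, SIRPA, GPR143 and CASP1 rose with each, as did BATF, an AP-1 family transcription factor (0.0689 FPKM with shGFP, 4.62 with sh1, 6.22 with sh2), and TTYH2 (log2 changes 2.06 and 2.08). THBS1, TGFBI, NT5E and PRMT1 itself fell with each. KYNU, an enzyme of tryptophan breakdown, fell (-1.56 and -1.83), as did the death receptor TNFRSF21 (-1.68 and -1.64), the retrotransposon-derived PEG10 (-1.32 and -1.52) and the ferlin MYOF (-1.62 and -1.28). ECHDC2 (-1.65 and -1.67) and the homeobox gene PRRX1 (-1.36 and -1.26) met the rule, but each call was lost without single libraries, without shGFP replicate 3 in both genes. Over its transcripts listed in every library ECHDC2 changed by -0.92 with each hairpin. A further 76 genes were called with both hairpins in opposite directions, 47 of them lower with sh1 and higher with sh2. Over all tested genes, which are not independent replicates, the log2 changes with sh1 and sh2 had a Pearson r of 0.646, against 0.599 in simulated groups without effects that shared the same controls. Their covariance was 0.142 against 0.0279, a difference of 0.114. The simulation gave on average 0.01 and at most 1 gene called with both, and independent lists of these sizes would share 142 higher and 149 lower genes. A split of the controls would leave 1 library per hairpin, so the controls were not split, and part of the excess in shared calls may come from the shared controls. Against the mean of both hairpins, 2390 genes were called (1181 higher and 1209 lower), 1021 when the 6 knockdown libraries were fitted as a single group, 1332 and 1356 without shGFP replicate 2 and 3, 1506 with all 9 libraries and their zeros as values, and 2630 with shGFP replicate 1 only where listed.

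**Figure D3:**
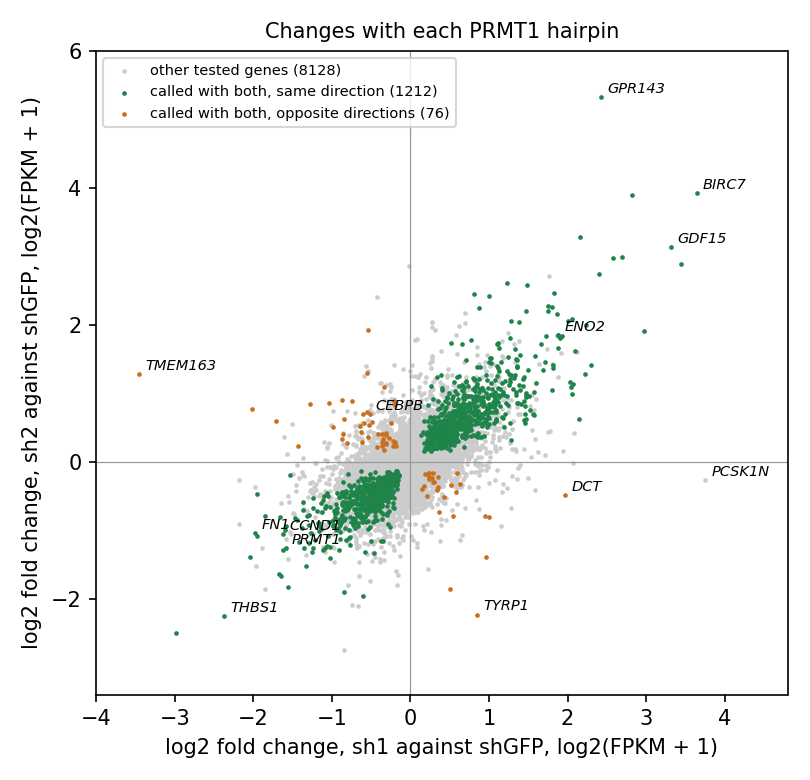
Log2 fold change against shGFP with sh1 (horizontal) and sh2 (vertical) for the 9416 tested genes, on the log2(FPKM + 1) scale; green points were called with both hairpins in the same direction (1212) and orange points in opposite directions (76). TYRP1 and DCT lie to the right of and below 0, and TMEM163 to the left of and above 0.

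Among the lists called with neither hairpin by camera, single members still changed. Of all tested genes, 24.2% were called with sh1 and 25.5% with sh2. These shares take both directions together, 1163 genes higher and 1115 lower with sh1, and 1146 and 1257 with sh2. Where rises and falls of a list together come near that share, its members were called about as often as other genes. This holds here and in the paragraphs above and below. The split between rises and falls can still differ from that of other genes. Of 20 tested G1/S genes, 2 rose and 5 fell with sh1 (2 and 6 adjusted over the list alone), and 4 rose and 4 fell with sh2 (4 and 6). CDKN1A, the inhibitor p21, rose from 4.36 to 14.4 FPKM with sh2 (log2 change 1.52) and was at 5.53 with sh1 (adjusted p = 0.17). CDKN1B, the inhibitor p27, rose by 0.69 with sh1 and 0.22 with sh2, the sh2 call lost in 6 of the 8 fits that left out a library. Of 14 p53 targets, 3 rose with sh1 and 5 with sh2 and none fell (3 and 5 adjusted over the list alone), with GADD45A, a damage-response gene, at 0.82 and 1.09. Of 8 arginine methyltransferase genes, 2 rose and 2 fell with each hairpin, the targeted PRMT1 among the falls (3 and 2 with sh1 and 2 and 2 with sh2 adjusted over the list alone). PRMT6 rose by 0.71 with sh1 and 0.52 with sh2; over its transcripts listed in every library it changed by 1.11 and 0.68, and the sh2 call was lost (adjusted p = 0.11). Of 25 RGG-motif RNA-binding PRMT1 substrates, 2 rose and 3 fell with sh1 (2 and 3 adjusted over the list alone), and 1 rose and 4 fell with sh2 (1 and 3). G3BP1, a stress granule protein, fell (-0.52 and -0.50). Of 16 EGFR and MAPK feedback genes, 2 rose and 5 fell with sh1 (3 and 6 adjusted over the list alone), and 4 rose and 3 fell with sh2 (4 and 3). Of 20 apoptosis regulators, 3 rose and 3 fell with sh1 (3 and 4 adjusted over the list alone), and 5 rose and 2 fell with sh2 (5 and 2). HRK, a BH3-only activator, rose by 1.51 and 0.97, and BCL2A1, an inhibitor, rose by 1.25 with sh2.

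Of 24 integrated stress and unfolded protein response genes, 6 fell with sh1 (6 adjusted over the list alone), and 3 rose and 4 fell with sh2 (3 and 4). ASNS, asparagine synthetase, fell (-0.60 and -0.59). Of 23 sterol and fatty acid synthesis genes, 4 rose and 4 fell with sh1 (4 and 4 adjusted over the list alone), and 4 rose and 6 fell with sh2 (4 and 7). INSIG1, a brake on sterol synthesis, fell (-1.07 and -0.65). Of 8 protease and metastasis genes, 1 rose and 3 fell with sh1 (2 and 4 adjusted over the list alone), and 2 rose and 2 fell with sh2 (3 and 2). TIMP3, a metalloprotease inhibitor, fell (-1.37 and -0.70). Of 10 senescence-associated genes, 2 rose and 2 fell with sh1 (2 and 2 adjusted over the list alone), and 3 rose and 2 fell with sh2 (4 and 2); LMNB1, lamin B1, fell (-0.63 and -0.44). Of 18 homologous recombination and Fanconi genes, 1 rose and 1 fell with sh1 (0 and 1 adjusted over the list alone), and 3 fell with sh2 (3). Of 9 Wnt pathway genes, 1 rose and 1 fell with sh1 (2 and 1 adjusted over the list alone), and 2 rose with sh2 (2). Of 7 NF-kB targets and cytokines, 1 rose and 2 fell with sh1 (1 and 2 adjusted over the list alone) and 0 passed with sh2 (0). Of 10 histone genes whose transcripts lack a poly(A) tail, 0 passed with sh1 (0 adjusted over the list alone) and 1 fell with sh2 (1).

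Of 3 tested epithelial genes, 1 rose with sh1 and 1 fell with sh2 (1 with sh1, and 1 up and 1 down with sh2, adjusted over the list alone); this was the splicing factor gene ESRP1, at 1.00 with sh1 and -0.80 with sh2. Of 6 tested luminal breast markers, MLPH, which links melanosomes to a motor protein, rose from 1.52 to 5.95 FPKM with sh1, and 0 passed with sh2 (1 and 0 adjusted over the list alone). Of 10 immediate early and heat shock genes, 2 rose and 1 fell with each hairpin (2 and 1 adjusted over the list alone). Of 15 housekeeping genes, 3 rose and 2 fell with sh1 (4 and 2 adjusted over the list alone), and 3 rose and 1 fell with sh2 (3 and 1). ACTB fell (-0.41 and -0.42) and GAPDH rose by 0.32 and 0.58. The fibroblast, endothelial, leukocyte and mitochondrially encoded lists had 1, 2, 0 and 0 tested genes; of these, FLT1, the VEGF receptor, fell (-1.30 and -1.18), ENG fell by 0.48 with sh1, and LUM rose by 1.73 with sh2, a call lost without either shGFP replicate or sh2 replicate 1.

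The last comparison set the hairpins against each other. TYRP1 and DCT, enzymes of melanin synthesis, were lower with sh2 than with sh1, and S100A4 and FN1 were higher. In all, 1931 genes differed, 919 higher and 1012 lower with sh2. TMEM163 was at 29.2 FPKM with sh2 and 0.129 with sh1 (log2 difference 4.74, SE 0.12), GPR143 at 43.7 and 4.98 (2.91), the potassium channel gene KCNN4 at 9.98 and 0.559 (2.83), ADAM19 at 31.3 and 3.68 (2.78) and the microfibril gene MFAP2 at 24.6 and 3.64 (2.47). PCSK1N was at 0.484 FPKM with sh2 and 23.0 with sh1 (-4.02), TYRP1 at 49.0 and 423 (-3.08), DCT at 49.9 and 280 (-2.46) and C1orf21 at 2.10 and 14.8 (-2.36). RNASEH2C met the rule (-2.34), but over its transcripts listed in every library it changed by 0.13 with sh1 and 0.01 with sh2. Of the 16 mesenchymal genes, 7 were higher and 1 lower with sh2 (7 and 1 adjusted over the list alone; camera adjusted p = 0.021, and adjusted p = 0.29 with an estimated correlation), with S100A4 higher by 1.34 and FN1 by 0.93. The melanocyte list, with 4 genes higher and 9 lower, did not pass (4 and 11 adjusted over the list alone; camera adjusted p = 0.12, and 0.19 over the 15 genes not seen beforehand). Without sh2 replicate 1 the count was 1175, without sh2 replicate 3 it was 1238, and with all 9 libraries and their zeros as values it was 664; with replicate 1 of shGFP used only for genes it lists it was 1851.

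The libraries, labelled as breast cancer cells, listed melanocyte lineage genes at high levels in every group. SOX10, a neural crest transcription factor, was at 250, 334 and 344 FPKM with shGFP, sh1 and sh2. MITF, the master transcription factor of melanocytes, lay between 44.0 and 71.8 FPKM over the 8 libraries and TYR, the rate-limiting enzyme of melanin synthesis, between 97.0 and 138. PMEL was at 211, 754 and 563 FPKM and TYRP1 at 234, 423 and 49.0. Of the 25 lineage genes, 18 were at 1 FPKM or more in all 8 libraries, and of the 20 genes not seen before the list was written, 15 were. Of the 18 keratin and epithelial surface genes, 16 were below 1 FPKM in all 8 libraries and 7 were listed at 0 in all 8, KRT8 and KRT19 among them, while KRT18 was at 40.8, 43.1 and 46.0 FPKM. A listed 0 may be a failed estimate in this table.

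**Figure D4:**
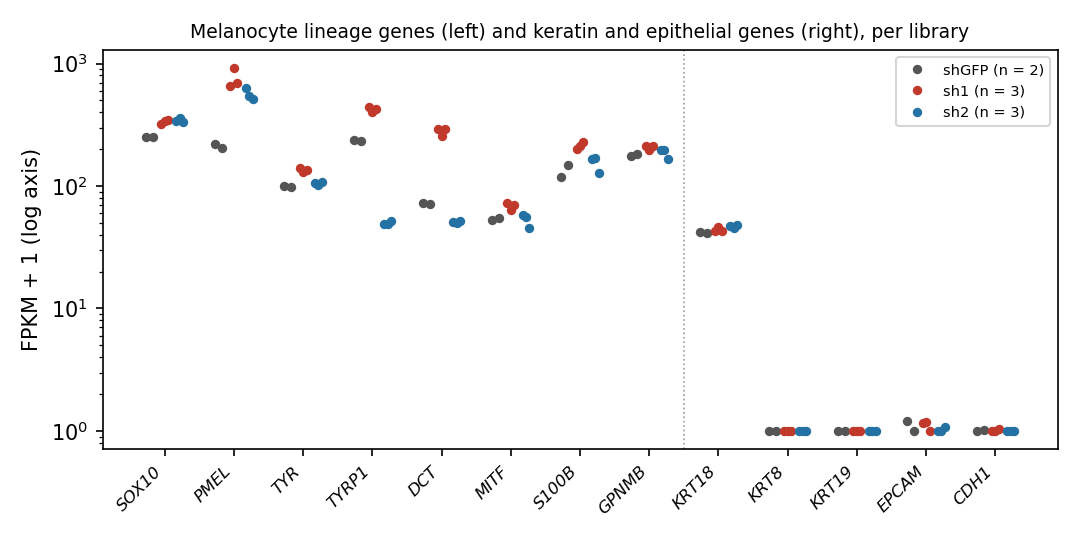
FPKM + 1 on a log axis for 8 melanocyte lineage genes (left of the dotted line) and 5 keratin and epithelial genes (right), in the 2 shGFP, 3 sh1 and 3 sh2 libraries used in the fits; each point is a library. SOX10 lies between 248 and 361 FPKM, and KRT8 and KRT19 are listed at 0 in all 8.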

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

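No test in this part was chosen after its own value was seen, but the tests were written after the gene counts and the most changed genes, some with opposite directions, had been seen. Every result here was singled out because the effects of the hairpins differed in the limma test of sh2 against sh1 or, for the mesenchymal list, in camera; values are log2 differences, sh2 minus sh1.

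Among the study's own genes, PRMT1 differed by 0.32 and CCND1 by 0.57, and the C/EBP family member CEBPB by 1.22, with a fall with sh1 and a rise with sh2. ESRP1 differed by -1.80, with a rise with sh1 and a fall with sh2. The mesenchymal list had a median difference of 0.39 (7 of 16 genes higher with sh2; camera adjusted p = 0.021, and adjusted p = 0.29 with an estimated correlation).

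Higher with sh2 were TMEM163 (4.74), GPR143 (2.91), KCNN4 (2.83), ADAM19 (2.78), MFAP2 (2.47), NRCAM (1.91), GALNT1 (1.61), CASP1 (1.13), EEF1A2 (1.07), FN1 (0.93), NT5E (0.64), SIRPA (0.40) and BIRC7 (0.28). Lower with sh2 were PCSK1N (-4.02), TYRP1 (-3.08), DCT (-2.46), C1orf21 (-2.36), RNASEH2C (-2.34), FAIM3 (-1.90), RUNX1 (-1.44), PCM1 (-1.36), VTI1B (-1.35), SYNGR1 (-1.07), MAF (-1.04) and BST2 (-0.56). Over transcripts listed in every library, SIRPA differed by 0.36, close to its main value, but did not pass (adjusted p = 0.14), RNASEH2C, PCM1 and VTI1B differed by -0.12, -0.46 and -0.09 and did not pass (adjusted p = 0.52, 0.18 and 0.68), and RUNX1 differed by -0.84.

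The pattern weighed here is the 1931 genes that differed between the hairpins. PRMT1 was lower with sh1, so a dose effect would have most of these genes further from shGFP with sh1. This held for 49.7% of them (95% exact binomial interval 47.5% to 52.0%, which treats genes as independent), and the tables argue against PRMT1 level as the whole cause. Of the 1931 genes, 47.2% (912 genes) were called with sh2 and not sh1, or were called and lay to opposite sides of shGFP, which is consistent with changes specific to a hairpin or to the cells that received it. Off-target silencing, clonal or culture differences and a biological response to PRMT1 dose in part of the genes stay open. The real split called 1786 genes when fitted alone and the highest of the other 9 called 1; with 10 splits in all, 1 of which was as large, no share under 0.05 was possible.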

How the results depend on the processing

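The fit with all 9 libraries and zeros as values was the design fixed beforehand. Leaving out shGFP replicate 1, using it only where listed, and the alternatives on listed zeros and the melanocyte list were chosen after the data were seen; the others were planned. PRMT1 and CCND1 stayed lower than shGFP and past the threshold with both hairpins under all 19 alternatives and all 8 fits without a library; the CCND1 difference between hairpins did too. FPKM carries no read number, so a planned count-model alternative was not run, and the precision set by depth is unknown.

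With all 9 libraries and zeros as values, the median log2 change of all genes moved to 0.45 with sh1 and 0.44 with sh2, and counts were 1242 (sh1), 1337 (sh2), 639 (both), 1506 (mean) and 664 (sh2 against sh1), r was 0.795 and the PRMT1 difference of 0.32 did not pass (adjusted p = 0.054). Of its calls, 1167 with sh1 and 1278 with sh2 were also among the main calls. With shGFP replicate 1 used only where listed, counts were 2422, 2513, 1335, 2630 and 1851, with 2152 of the sh1 and 2248 of the sh2 calls among the main calls. The PRMT1 difference was 0.23 for transcripts tested separately and did not pass (adjusted p = 0.17). The mean count was 1021 in a 2-group fit. At a log2 change of at least 1 the counts were 313, 303, 118, 244 and 189, and at an adjusted p of 0.01 they were 1018, 1105, 482, 1172 and 816, by construction fewer.

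Leaving out each library in turn gave 1343 to 2057 calls with sh1, 1447 to 2442 with sh2, 704 to 1091 with both, 1332 to 2302 for the mean and 1175 to 1790 between hairpins, and r from 0.62 to 0.70. PRMT1 ranged from -1.64 to -1.53 (sh1), -1.32 to -1.21 (sh2) and 0.28 to 0.37 (between), and CCND1 from -1.69 to -1.52, -1.09 to -1.02 and 0.46 to 0.63. Counts moved over 1.5 times without shGFP replicate 2 (1362, 1447, 707 and 1332 for sh1, sh2, both and mean) or shGFP replicate 3 (1343, 1460, 704 and 1356), when the lone control was assumed to vary like the other groups, and between hairpins without sh2 replicate 1 (1175) or 3 (1238). The main fit is itself the fit without shGFP replicate 1.

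Directions reversed with transcripts tested separately and with always-listed transcripts only: RNASEH2C with sh2 (0.0069), AURKA with sh2 (0.080), AMOTL2 with sh1 (0.050), PFKFB3 with sh1 (-0.077) and ERBB2 with sh1 (0.45); dropping switching transcripts from the sums makes this change. They reversed with all 9 libraries and zeros as values for RNASEH2C with sh2 (0.35), CEBPZ with sh1 (1.46) and AURKA (0.59 and 0.54), none past the threshold there. Of all these, only ERBB2 passed after the reversal (adjusted p = 0.027 and 0.022), from a main value of -0.06 that did not pass. Of 40 genes named by the first 4 parts of the rule, 8 lost a call without some single library: C1orf21, ECHDC2, GALNT1, MFAP2, PCM1, PRRX1, RNASEH2C and VTI1B. List calls lost without a single library were those of the study genes with sh1 and with sh2, the mesenchymal genes with sh2, the ribosomal genes with sh2 and, without shGFP replicate 3, the ribosomal and hypoxia genes with the mean (adjusted p = 0.085 each).

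Deviations of same-numbered libraries correlated positively but weakly, at 0.0076 to 0.081, under the 0.1 set for pairing, and 6 of 8 libraries matched their own number best, a hint from the data and not the design. With the number as a block, counts were 1727, 1893, 909, 1834 and 1557, and the list calls for the study genes with sh1, sh2 and their mean, the mesenchymal genes with sh2 (0.089) and the hypoxia genes with the mean (0.054) were lost.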

Other observations

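The tests on shGFP replicate 1 were chosen after its listing pattern had been seen, and the median over all 25 lineage genes after the other lineage values; the lineage test was written after 5 of the 25 genes had been noticed, and the G1/S test after the fall of CCND1 itself was known.

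FOSL1, an AP-1 subunit of invasive cells, fell from 113 to 37.0 FPKM with sh1 and 58.6 with sh2 (log2 changes -1.58 and -0.93), and JUN fell (-0.46 and -0.70). EGR1, an immediate early transcription factor, rose by 1.13 and 1.67, and FOS by 0.45 with sh2, a call lost without shGFP replicate 3. Of the G1/S list, RB1 fell (-0.60 and -0.43), the sh2 call lost without either shGFP replicate and both calls lost with shGFP replicate 1 used where listed (adjusted p = 0.16 and 0.45), while CCND3 rose by 0.21 and 0.39, the sh1 call lost without either shGFP replicate and without 3 other libraries. In the lineage set, QPCT rose by 0.65 and 1.05, and the calpain gene CAPN3 by 1.93 and 1.84.

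Melanocyte lineage genes stood high in every library although the label is a breast line. A small admixture of melanocytic cells in some libraries would make the lineage genes vary several-fold and sit low; library medians over the 21 genes above 0 in all 8 libraries differed by 1.57-fold, from 63.6 to 99.9 FPKM (over all 25 genes by 1.70-fold, from 40.9 to 69.4), against medians of 14.2 to 14.4 for all tested genes, which argues against it. That 18 of 25 lineage genes, and 15 of the 20 not seen beforehand, were at 1 FPKM or more in all 8 libraries is consistent with cells of melanocytic lineage in all 3 groups, a hypothesis that expression alone cannot settle and that names no line. A steady admixture in all libraries, or lineage genes switched on in breast cells, stays open and untested.

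Genes counted as listed in shGFP replicate 1, with no transcript at 0 that was above 0 in all other libraries, were an uneven sample. Within expression deciles, genes called with either hairpin were listed there more often than others, with a Mantel-Haenszel odds ratio of 3.51 (95% interval 3.21 to 3.85), at least 2.85 in each decile. Lower depth was predicted to give equal listing at matched expression. The deciles matched FPKM, not read number, and genes with more reads can be both called and listed more often. The value therefore cannot tell lower depth from a column filled only for genes the authors tested or called as changed. No source used here records such a step.

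Further readings were tested. If CCND1 fell as part of a fall of the whole G1/S list, the median of the other 19 tested members would have fallen too. That median log2 change with the mean of both hairpins was -0.12 (SE 0.14), against -1.34 for CCND1, which argues against a like fall of the whole list. The list mixes cyclins and CDKs with inhibitors such as CDKN1A and CDKN1B, which need not fall with them. The median therefore cannot decide on a fall shared by the cyclins and CDKs alone. For the genes changed with both hairpins averaged, 1 of 28 splits of the 8 libraries into 6 and 2, the real split, gave as many calls. It gave 1021 and the highest other gave 4. Every other split cut across a group, so the real split would rank first whenever the cultures differed for any reason. The result speaks only against all 8 libraries varying alike, and cannot tell knockdown from another difference of the control culture.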
